A study of Homo sapiens with 8 samples.

How the data were processed

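Total RNA of HEL cells, a human erythroleukaemia line, was measured on 8 Affymetrix expression arrays. Cells had been exposed for 48 h to vehicle (DMSO, the control), to 0.5 µM LY2784544, to 20 µM GRN163L or to both agents, and each treatment was made once in each of 2 separate experiments, so that every group holds 2 arrays. The doses used in the combination are not restated for that arm in the labels. Reading the combination against 1 agent as the effect of the other takes these doses to equal those given alone. Per the labels' protocols, 150 ng of Trizol-extracted total RNA was amplified to sense-strand DNA, fragmented and biotinylated with Affymetrix kits.

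The deposited values are log2 signals, 1 per probe set and array. Per the submitters' processing notes they were made by the authors with RMA (robust multi-array average, which subtracts background, quantile-normalizes the arrays and summarises the probes of a probe set) in Affymetrix Expression Console. The program's version, the genome build behind the probe sets and whether all 8 arrays were normalized in 1 run are not given in the sources used here. The log base was taken as 2 from the range of the values and the use of RMA. The table holds 33297 probe sets with values rounded to 2 decimals, and the array medians lay between 5.07 and 5.25. RMA compresses large differences between dim probe sets and forces the arrays to nearly one distribution of signals, so a change of most transcripts in one direction would be reduced in these values. No array was a copy of another: the share of probe sets with the same rounded value on 2 arrays was at most 1.90%.

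Probe sets were named with the platform annotation held by GEO. Exactly 1 gene was named by 19181 probe sets and several genes by 2055, while 12061 probe sets were in no row of that annotation and stay unnamed here. The NCBI gene number of 19143 of the 1-gene probe sets was found in the RefSeq gene table given for human, and no symbol needed updating. The 1-gene probe sets covered 17958 genes, of which 895 had more than 1 probe set. The probe set with the highest mean over the 8 arrays stood for its gene. Genes whose mean lay under the 30th percentile (4.37 on the log2 scale) were left out, which left 12570 genes.

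A linear model with 4 group means was fitted to all 8 arrays with limma (version 3.58.1 in R 4.3.3) and tested with empirical Bayes moderation. The 6 contrasts were each agent and the combination against control, the combination against each agent, and the interaction, which is the combination's difference from LY2784544 minus the difference of GRN163L from control. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 within its contrast. The residual degrees of freedom were 4, and the moderation added 4.65. The labels name the first and the second experiment for each array, so the replicate number marks a shared experiment and pairs the arrays. Deviations from the group means correlated across genes between arrays of the same experiment with r = 0.67 for LY2784544 and the combination, 0.39 for GRN163L and the combination, 0.26 for LY2784544 and GRN163L, and 0.10 to 0.19 for control with each of the others. The fit with the experiment as a block found 31 genes that differed between the experiments. The labels do not say what separated the experiments beyond being made apart, so p-values measure the spread between these cultures and arrays.

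The 29 gene lists, written before the data were examined, were tested with limma's cameraPR at its preset correlation of 0.01, which compares a list's statistics with those of all other genes. They cover JAK-STAT and MAPK targets, stress responses, metabolism, the cell cycle, telomere genes and markers of blood cell types. Each list's p was adjusted over the lists within a contrast. Camera with an estimated correlation, and fry, a rotation test of whether a list's genes move one way on balance, were the alternatives. The named genes were chosen by a rule fixed before the data were examined. In each comparison with control it took the 10 genes with the largest rise and the 10 with the largest fall. These had to be called and of the same sign in both experiments. In the other contrasts it took the 5 largest in each direction on the same condition. Where none passed, it took the 3 with the smallest p in each direction. It also took up to 4 members with the smallest p of each list described. For the drug targets it took JAK2 and TERT, but not TERC, the RNA template of telomerase. Genes named outside the rule are said to be chosen after their values were seen.

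Alternatives fixed before the data were examined were the experiment as a block, no filter or a filter at the 50th percentile, a fit on the compared groups only, a mean-variance trend, robust moderation, median or quantile normalization of the tested genes, the mean of a gene's probe sets, a 2-fold minimum, array weights and leaving out each array in turn. Leaving out an array leaves its group with 1 array, which is then assumed to vary like the others. An olfactory receptor covariate and the joint removal of the LY2784544 and combination arrays of experiment 1 were added after seeing the data. With values simulated for LY2784544 against control over 12570 genes in 20 draws, the fit recovered 75.1% of 2-fold and 99.7% of 4-fold changes, 6.17% of its calls were false and the unchanged contrast gave a mean of 0 calls. The simulated noise was independent between genes and arrays, without the shared deviations of one experiment. These rates may therefore not hold for the real arrays. Overlaps between comparisons that share the control arrays were set beside 100 draws of unchanged groups, and their covariance was also taken across experiments, a setting added after seeing the data. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The number of arrays, 2 per group, limits the precision of every value.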

Results

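The 8 arrays measured transcript levels in HEL cells, which depend on an activated JAK2 kinase, after 48 h with vehicle, the JAK2 inhibitor LY2784544, the telomerase inhibitor GRN163L or both agents. Each of the 4 groups held 2 arrays, 1 from each of 2 separate experiments, and values are log2 RMA signals given as mean ± SD over the 2 arrays. The median of the tested genes was 7.48 and 7.46 on the control arrays, 7.33 and 7.41 with LY2784544, 7.46 and 7.51 with GRN163L, and 7.23 and 7.36 with the combination, in experiments 1 and 2. Setting all arrays to one median would move LY2784544 against control by 0.103, the combination against control by 0.175 and the combination against GRN163L by 0.19 on the log2 scale. All 43 calls of gene lists given here kept their direction against other genes and their call on that scale. Camera sets a list against all other genes, and one median moves both alike, so these calls were nearly bound to stay. They do not show that the median changes of the lists against control keep their size. In a principal component analysis the first component held 40.7% of the variance. On it lay the controls at -23.1 and -23.4, GRN163L at -8.08 and -15.2, LY2784544 at 22.0 and -1.23, and the combination at 37.0 and 11.9. JAK2 and TERT, which the rule named for the drug targets, were called in no comparison. JAK2 was at 10.44 ± 0.55 in control and 10.49 ± 0.04 with LY2784544 (limma adjusted p = 0.957). TERT was at 4.89 ± 0.13 in control and 4.64 ± 0.33 with GRN163L (adjusted p = 0.995), near the filter level of 4.37. TERC, the RNA template of telomerase, was at 9.42 ± 0.23 in control, 8.755 ± 0.26 with GRN163L and 8.19 ± 0.34 with the combination. It fell in the combination against control and is named here after its values were seen.

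LY2784544 against control asked how HEL cells respond to inhibition of JAK2. Of 12570 genes, 49 rose and 111 fell. SOCS3, a feedback inhibitor induced by JAK-STAT signalling, fell from 8.35 ± 0.09 to 7.23 ± 0.18 (log2 change -1.12, SE 0.18, adjusted p = 0.0251), and BCL3, a nuclear cofactor of NF-kB, fell from 8.78 ± 0.11 to 6.44 ± 0.14 (-2.34, SE 0.16, adjusted p = 0.00234). The largest fall was that of BNIP3, a mitophagy receptor induced by hypoxia, from 11.20 ± 0.50 to 8.21 ± 0.62 (-2.99, SE 0.39, adjusted p = 0.0112). PPBP, which encodes a platelet chemokine, rose from 5.93 ± 0.30 to 8.45 ± 0.04 (2.52, SE 0.23, adjusted p = 0.00371), and LYVE1, a hyaluronan receptor, rose from 4.41 ± 0.16 to 7.45 ± 0.17 (3.04, SE 0.30, adjusted p = 0.00458).

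Further large falls were those of SEPTIN10 (-2.42), IFITM3 (-2.40), ANGPT2 (-2.34), ADA (-2.30), GSDME (-2.30), SMAD3 (-2.27), PRF1 (-2.26) and ERO1A (-2.24). Further large rises were those of MAS1L (2.78), ZNF595 (2.77), SLC37A2 (2.43), ANKFN1 (2.34), HTRA3 (2.19) and UCA1 (2.01), with REXO1L1P (2.94) and REXO1L2P (2.19), members of a repeated family with near-identical copies, so that the gene behind each signal is uncertain. All 160 called genes changed in the same direction in both experiments, with a median absolute change of 1.30. With 2 arrays per group a gene of opposite directions could hardly be called, so this is no separate replication. Of the 49 genes that rose, 27 had a control level below 6, against 27.2% of the genes tested. Over 356 olfactory receptor genes, most of which blood cells do not use, the array median was 3.25 and 3.28 in control and 3.50 and 3.41 with LY2784544.

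Among the gene lists, 18 hypoxia and glycolysis genes were all lower with LY2784544, with a median of -0.74 (adjusted p = 1.09e-13, adjusted p = 0.354 with an estimated correlation). The median was -1.035 in experiment 1 and -0.455 in experiment 2. BNIP3, P4HA1 (-2.18) and ALDOC (-2.01), a collagen hydroxylase and a glycolytic aldolase, fell over all genes tested, and 14 members fell when adjusted over the list alone. Of 17 JAK-STAT target genes 16 were lower, with a median of -0.48 (adjusted p = 1.52e-04, adjusted p = 0.249 with an estimated correlation). SOCS3 fell, PIM1, an oncogenic kinase, was at -0.67 (adjusted p = 0.0991, not called), and 5 members fell when adjusted over the list alone. Of 19 integrated stress response genes, which ATF4 induces, 17 were higher, with a median of 0.53 (adjusted p = 1.09e-13, adjusted p = 0.181 with an estimated correlation). CHAC1 (1.33), SLC7A11 (1.28), SESN2 (1.30) and PSAT1 (1.37) rose, and 10 rose when adjusted over the list alone. Of 21 megakaryocyte and platelet genes 15 were higher, with a median of 0.24 (adjusted p = 8.50e-05, adjusted p = 0.181 with an estimated correlation), and PPBP and CLEC1B (0.99) rose.

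Lysosome genes were higher with LY2784544 (16 genes, median 0.21, adjusted p = 9.04e-04, adjusted p = 0.354 with an estimated correlation) with no member called. Cholesterol synthesis genes were lower (14 genes, median -0.49, adjusted p = 0.00655, adjusted p = 0.736 with an estimated correlation). MAPK feedback and immediate early genes were also lower (16 genes, median -0.46, adjusted p = 0.0239, adjusted p = 0.736 with an estimated correlation), by -0.095 in experiment 1 and -0.785 in experiment 2. No member of these 2 lists was called. With each array's olfactory receptor median as a covariate, chosen after seeing the data, the cholesterol median was 0.029. That covariate takes its slope from differences between the experiments, 96.3% of it on the LY2784544 and combination arrays, so that it also removes other differences between the experiments. Of 9 lymphocyte genes, the B cell receptor genes CD79A (-1.39) and CD79B (-1.02) fell (list median -0.32, adjusted p = 0.0194, adjusted p = 0.354 with an estimated correlation). The 20 G2 and mitosis genes had a median of -0.84 in experiment 1 and 0.035 in experiment 2 (adjusted p = 0.0250, adjusted p = 0.834 with an estimated correlation), with no member called. The median was -0.020 without the LY2784544 array of experiment 1 and 0.843 with the covariate, which would turn a list low in experiment 1 only whatever the cause. The 15 NF-kB and inflammatory genes (median -0.46) passed only with the experiment as a block (adjusted p = 0.0242, against 0.126 without it).

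With the experiment as a block, LY2784544 against control gave 99 higher and 246 lower genes, the first 160 among them, while median normalization gave 63 higher and 89 lower. The count of 160 fell to 0 without the control array of experiment 2, to 20 without that of experiment 1, to 58 without the LY2784544 array of experiment 1, to 76 without either GRN163L array, and to 44 with the covariate.

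**Figure D1:**
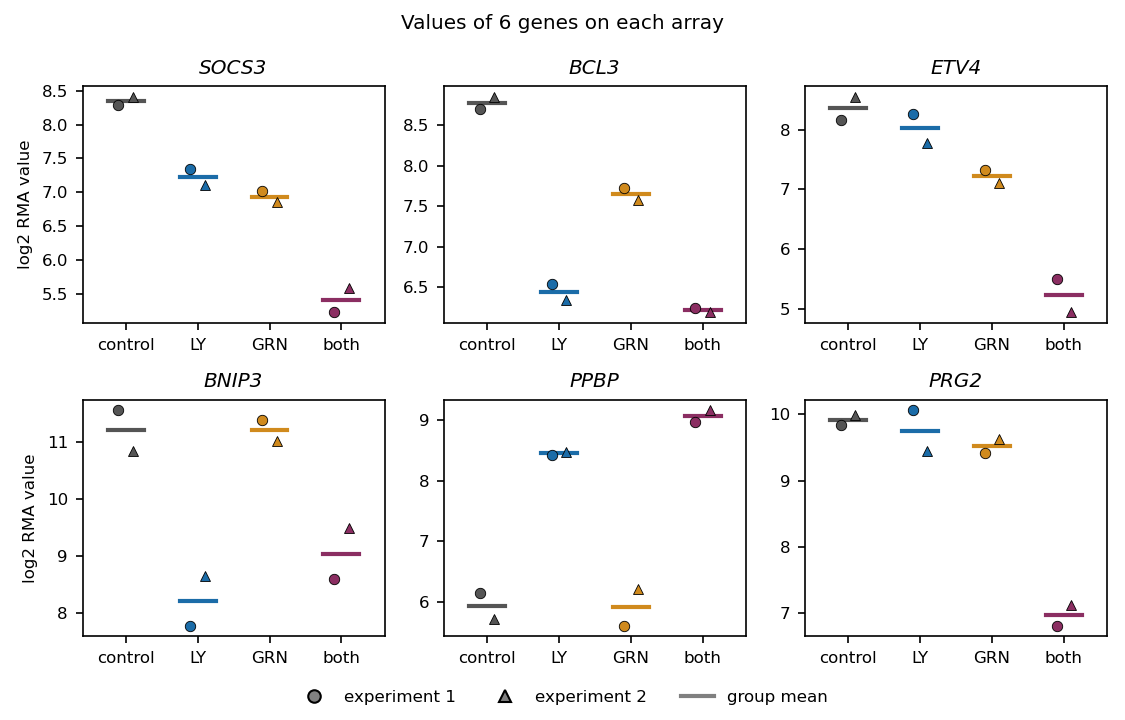
Log2 RMA values of SOCS3, BCL3, ETV4, BNIP3, PPBP and PRG2 on each of the 8 arrays, by group, with experiment 1 as circles, experiment 2 as triangles and the group mean as a bar; each panel has its own vertical scale, which does not start at 0. SOCS3 averaged 8.35 in control, 7.23 with LY2784544, 6.93 with GRN163L and 5.41 with both.

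GRN163L against control asked how the cells respond to the telomerase inhibitor. No gene was called by limma, with the experiment as a block or without it, and 595 genes had an unadjusted p below 0.05, 309 of them higher and 286 lower, against 628 expected by chance if no gene changed. The fit takes 1 spread from all 4 groups, so a count below the 628 expected does not show that no gene changed. The smallest adjusted p was 0.201. The genes with the smallest p among those lower were TNFRSF9, a costimulatory receptor (-1.29, SE 0.16), SOCS3 (-1.42, SE 0.18) and BCL3 (-1.13, SE 0.16), each with an adjusted p of 0.201. Those higher were SLC22A20P (1.34, SE 0.19, adjusted p = 0.201), LINC03030 (1.15, SE 0.17, adjusted p = 0.201) and MAPK4 (1.81, SE 0.30, adjusted p = 0.233). All 6 had the same sign in both experiments, which their choice by smallest p favours.

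All 23 replication-dependent histone genes, which are transcribed mainly in S phase, were lower with GRN163L, with a median of -0.59 (adjusted p = 4.44e-19, adjusted p = 0.552 with an estimated correlation). Their values included -1.14 for H2AC4, -0.86 for H3C3 and -0.72 for H3C8. Of 19 integrated stress response genes 18 were higher, with a median of 0.46 (adjusted p = 4.02e-12, adjusted p = 0.281 with an estimated correlation), among them ASNS (1.24), SLC7A11 (1.08) and DDIT4 (0.94). When adjusted over the list alone, 6 histone genes fell and 5 integrated stress response genes rose. Lower as groups were the MAPK feedback and immediate early genes (median -0.56, adjusted p = 1.87e-06, adjusted p = 0.552 with an estimated correlation) and the JAK-STAT target genes (-0.20, adjusted p = 8.52e-06, adjusted p = 0.281 with an estimated correlation). So were the NF-kB and inflammatory genes (-0.32, adjusted p = 0.00672, adjusted p = 0.281 with an estimated correlation) and the hypoxia and glycolysis genes (-0.25, adjusted p = 0.0184, adjusted p = 0.691 with an estimated correlation). ETV4 was at -1.14, JUNB at -1.06 and PFKFB3 at -0.51 in this comparison, none of them called. Cholesterol synthesis genes were higher (median 0.18, adjusted p = 0.0184, adjusted p = 0.691 with an estimated correlation), with CYP51A1 at 0.82. The 25 DNA replication genes (median -0.12) passed only with the block (adjusted p = 0.0431, against 0.175).

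Fitting only the control and GRN163L arrays gave 6 called genes, as did leaving out the LY2784544 and combination arrays of experiment 1, an alternative chosen after seeing the data.

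The combination against control asked what both agents did together. Of 12570 genes, 95 rose and 341 fell. SOCS3 fell from 8.35 ± 0.09 to 5.41 ± 0.25 (-2.94, SE 0.18, adjusted p = 4.77e-04), BCL3 from 8.78 ± 0.11 to 6.22 ± 0.04 (-2.56, SE 0.16, adjusted p = 4.77e-04) and GSDME, a pore-forming gasdermin, from 7.75 ± 0.13 to 4.26 ± 0.17 (-3.48, SE 0.22, adjusted p = 4.77e-04). ETV4, a transcription factor induced by ERK signalling, fell from 8.36 ± 0.28 to 5.22 ± 0.40 (-3.13, SE 0.25, adjusted p = 0.00119), and PRG2, an eosinophil and basophil granule protein, from 9.91 ± 0.11 to 6.96 ± 0.22 (-2.95, SE 0.23, adjusted p = 0.00119). PPBP rose to 9.07 ± 0.13 (3.13, SE 0.23, adjusted p = 0.00119) and LYVE1 to 7.45 ± 0.41 (3.04, SE 0.30, adjusted p = 0.00379).

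The other large falls were those of ANGPT2 (-2.96), IL2RB (-2.86), CPA3 (-2.59), WNT11 (-2.58) and GSTP1 (-2.52). The other large rises were those of LINC00965 (2.67), OR51E1 (2.58), OR2AT4 (2.51), REXO1L1P (2.39), DAPP1 (2.30), ZNF595 (2.27), MAPK4 (2.22) and ANKRD20A11P (2.02). OR51E1 and OR2AT4 are olfactory receptor genes, and REXO1L1P and ANKRD20A11P belong to repeated families with near-identical copies. Of the 95 genes that rose, 36 had a control level below 6, and of the 341 that fell, 35, against 27.2% of the genes tested. The tendency of rising genes to low control levels holds here too. The olfactory receptor median was 3.53 and 3.37 on the combination arrays, against 3.25 and 3.28 in control. All 436 called genes had the same sign in both experiments, with a median absolute change of 1.13. Here too a gene of opposite signs could hardly be called.

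All 17 JAK-STAT target genes were lower with the combination, with a median of -0.62 (adjusted p = 2.02e-10, adjusted p = 0.132 with an estimated correlation). SOCS3, SOCS1, PIM1 (-1.32), PIM2 (-0.68) and ID1 (-1.65) fell, and 9 fell when adjusted over the list alone. All 16 MAPK feedback and immediate early genes were lower, with a median of -0.99 (adjusted p = 2.62e-08, adjusted p = 0.493 with an estimated correlation), of which ETV4 and ETV5 (-2.06) fell, and 11 fell when adjusted over the list alone. All 18 hypoxia and glycolysis genes were lower, with a median of -0.95 (adjusted p = 3.02e-12, adjusted p = 0.493 with an estimated correlation). Among its 8 called members were P4HA1 (-2.42), ALDOC (-2.44), the hexokinase gene HK2 (-1.74) and the glucose transporter gene SLC2A3 (-1.15), and 15 fell when adjusted over the list alone. Of the 23 histone genes, all lower with a median of -0.83 (adjusted p = 2.25e-10, adjusted p = 0.609 with an estimated correlation), 7 fell, among them H2BC3 (-1.81), H2AC4 (-1.58) and H2BC7 (-1.56), and 19 fell when adjusted over the list alone.

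Of 7 measured mast cell and basophil genes, PRG2, CPA3, KIT (-2.23) and HPGDS (-2.18) fell, and the list's median was -2.19 (adjusted p = 2.62e-08, adjusted p = 0.132 with an estimated correlation). The median was -2.87 in experiment 1 and -1.35 in experiment 2. The other measured members moved less. HDC was at 10.59 in control and 10.05 with the combination, GATA2 at 10.955 and 10.515, and FCER1A, which was higher, at 10.33 and 10.49. Of 21 megakaryocyte and platelet genes 19 were higher, with a median of 0.31 (adjusted p = 2.42e-09, adjusted p = 0.112 with an estimated correlation). PPBP, PF4 (1.92), CLEC1B (1.09) and MMRN1 (0.87) rose, and 6 rose when adjusted over the list alone. The integrated stress response genes were higher by a median of 0.19 (adjusted p = 0.00785, adjusted p = 0.570 with an estimated correlation), and SLC7A11 (1.37) rose. Members of this list went both ways. ASNS, SESN2 and PSAT1 had a higher mean than in control, and ATF3, TRIB3, PPP1R15A and CEBPB a lower one. The G2 and mitosis genes had a median of -1.01 in experiment 1 and -0.05 in experiment 2 (adjusted p = 0.0352, adjusted p = 0.900 with an estimated correlation) with no member called, and 0.771 with the olfactory receptor covariate, with the same limit. A further 3 lists passed only with the experiment as a block. These were the DNA replication genes (median -0.47, adjusted p = 0.00639 against 0.0916), the NF-kB and inflammatory genes (-0.43, adjusted p = 0.0188 against 0.130) and the lymphocyte genes (-0.18, adjusted p = 0.0261 against 0.0717), of which CD79A (-1.84) and CD79B (-1.32) fell.

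With the experiment as a block, 357 genes were higher and 1025 lower with the combination, while median normalization gave 174 and 184 and quantile normalization 129 and 220. The count of 436 fell to 57 without the control array of experiment 2, to 92 without that of experiment 1, to 109 without the combination array of experiment 1, to 143 without either GRN163L array, to 217 without the LY2784544 and combination arrays of experiment 1 and to 48 with the covariate, the last 2 settings chosen after seeing the data.

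**Figure D2:**
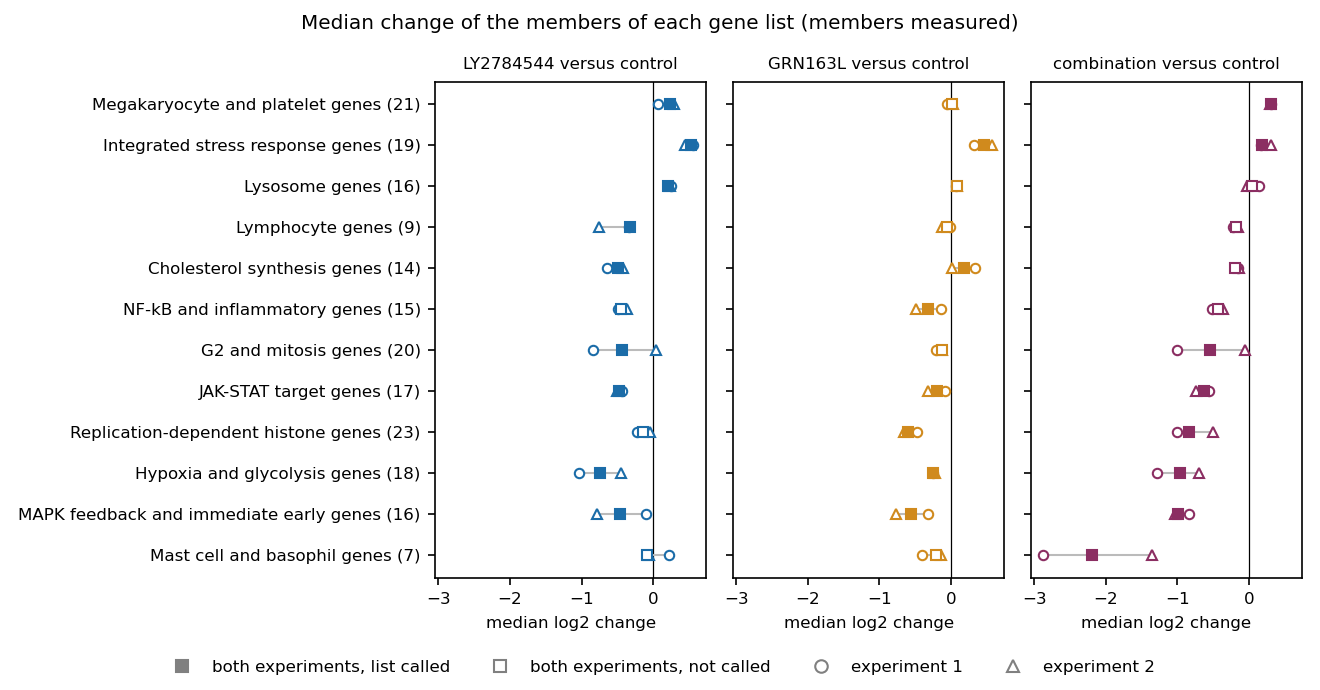
Median log2 change of the members of each gene list called in at least 1 comparison with control, for LY2784544, GRN163L and the combination, with the number of measured members in brackets; squares are the median of the changes over both experiments, filled where the list was called at the preset correlation, and circles and triangles are experiments 1 and 2. The histone median was -0.14 with LY2784544, -0.59 with GRN163L and -0.83 with both.

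The comparisons with control shared genes. LY2784544 and the combination had 14 called genes higher and 71 lower in common and 2 of opposite sign, against 0.37 and 3.01 from independent lists and a mean of 0.01 in 100 draws of unchanged groups with the same controls. The draws held no changed gene and so hardly any calls, and independent lists leave out the shared controls. Neither number shows how many called genes shared controls alone would put in common. The number in common was 0 without the control array of experiment 2 and at most 100 when another array was left out. Across genes, which are not independent replicates, the changes of LY2784544 and the combination had a covariance of 0.1098 against 0.024 from shared controls alone (r = 0.654 against 0.501). Those of GRN163L and the combination had a covariance of 0.0687 (r = 0.611). Those of LY2784544 and GRN163L had a covariance of 0.0288 against 0.024 (r = 0.311 against 0.5). Part of each excess may come from the shared controls, and the simulation also left out that arrays of one experiment deviated together (r = 0.67 for LY2784544 and the combination). Changes of one treatment in experiment 1 beside those of the other in experiment 2, a setting chosen after seeing the data, share neither controls nor an experiment. Their mean covariance was 0.0681 for LY2784544 and the combination, 0.0364 for GRN163L and the combination, and 0.0024 for LY2784544 and GRN163L.

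The combination against LY2784544 asked what GRN163L changed in cells that also had the JAK2 inhibitor. 10 genes were higher in the combination and 29 lower. SOCS3 was lower by a further 1.82 (log2 change -1.82, SE 0.18, adjusted p = 0.00531), ETV4 changed by -2.80 (SE 0.25, adjusted p = 0.00301), PRG2 by -2.79 (SE 0.23, adjusted p = 0.00301) and KIT, the stem cell factor receptor, by -2.79 (SE 0.39, adjusted p = 0.0284). SLC37A2, which rose with LY2784544, was at 9.08 ± 0.45 with that agent and 6.20 ± 0.47 with both (-2.88, SE 0.27, adjusted p = 0.00362), and GSTP1 changed by -2.75. SEPTIN10, which fell with LY2784544, was at 3.75 ± 0.47 with that agent and 5.53 ± 0.16 with both (1.77, SE 0.22, adjusted p = 0.0251). VGLL3 (1.71), SEC11C (1.80), LINC03030 (1.64) and B3GALNT1 (1.49) also rose.

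All 7 mast cell and basophil genes were lower in the combination than with LY2784544, with a median of -1.66 (adjusted p = 1.17e-14, adjusted p = 0.110 with an estimated correlation), and KIT and PRG2 fell over all genes tested and 5 when adjusted over the list alone. The list's median was -2.49 in experiment 1 and -0.82 in experiment 2. Of 8 stem and progenitor genes, CD34 (-2.40) and KIT, which is on both lists, fell, while MEIS1 was at 0.60 (list median -0.23, adjusted p = 0.00125, adjusted p = 0.336 with an estimated correlation). All 23 histone genes were lower with a median of -0.64 (adjusted p = 5.08e-12, adjusted p = 0.639 with an estimated correlation), and 13 fell when adjusted over the list alone. MAPK feedback and immediate early genes (median -0.58, adjusted p = 5.61e-05, adjusted p = 0.639 with an estimated correlation) and JAK-STAT target genes (-0.23, adjusted p = 2.73e-04, adjusted p = 0.336 with an estimated correlation) were lower as groups. So were the integrated stress response genes (-0.51, adjusted p = 2.73e-04, adjusted p = 0.336 with an estimated correlation) and DNA replication genes (-0.41, adjusted p = 0.0212, adjusted p = 0.950 with an estimated correlation). ETV4, ETV5 (-1.83) and SOCS3 fell among them, and the DNA replication median was -0.035 without the combination array of experiment 1. Cholesterol synthesis genes (0.32, adjusted p = 0.00222, adjusted p = 0.827 with an estimated correlation) and megakaryocyte and platelet genes (0.17, adjusted p = 0.00378, adjusted p = 0.333 with an estimated correlation) were higher. The BCL2 family apoptosis genes, with BMF at -1.18, passed only with the block (median -0.19, adjusted p = 0.0404, against 0.0783).

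With the block 71 genes were higher and 130 lower than with LY2784544, median normalization gave 18 and 31, quantile normalization 15 and 27, and a fit on these 2 groups alone 0. The count of 39 fell to 16 without either GRN163L array, 18 without either control array, 19 without the combination array of experiment 1 and 12 without the experiment 1 arrays of LY2784544 and the combination, and rose to 272 with the covariate.

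The combination against GRN163L asked what the JAK2 inhibitor changed in cells that also had GRN163L. 9 genes were higher in the combination and 59 lower. PPBP (3.15, SE 0.23, adjusted p = 0.00457), LYVE1 (2.86, SE 0.30, adjusted p = 0.0143), PF4, another platelet chemokine gene (2.06, SE 0.27, adjusted p = 0.0204), TRIM40 (1.29) and DNAJC5G (1.22) rose. PRG2 (-2.56, SE 0.23, adjusted p = 0.00580), GSDME (-2.50, SE 0.22, adjusted p = 0.00580), PRF1 (-2.42), ANGPT2 (-2.54) and CPA3 (-2.32) fell. Of 21 megakaryocyte and platelet genes 19 were higher, with a median of 0.37 (adjusted p = 1.48e-15), and PPBP, PF4 and MMRN1 (1.18) rose, with 5 when adjusted over the list alone. This was the only call of a list that held with an estimated correlation (adjusted p = 0.0452 with an estimated correlation). In the same comparison 22 of 25 olfactory receptor genes, a list chosen after seeing the data, were also higher. Their median was 0.485 (camera p = 2.7e-09, p = 0.0436 with an estimated correlation, neither adjusted). Against control, 21 of these 25 genes were higher with LY2784544 (median 0.405), 20 with GRN163L (0.085) and 23 with the combination (0.495). In the combination against LY2784544, 17 were higher (median 0.19). These 25 genes had passed the filter on the mean over all arrays. A dim gene raised on some arrays passes it more easily, so the filter favoured rises in these counts, medians and p-values. Without the filter, over 356 olfactory receptor genes, the array median was 3.53 and 3.37 with the combination in experiments 1 and 2. With GRN163L it was 3.32 and 3.3. The median change of the 25 genes between these groups was 0.77 and 0.2.

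All 18 hypoxia and glycolysis genes were lower in the combination than with GRN163L, with a median of -0.75 (adjusted p = 3.36e-12, adjusted p = 0.567 with an estimated correlation), and P4HA1 (-2.17) and ALDOC (-2.23) fell, with 11 when adjusted over the list alone. Of 17 JAK-STAT target genes 16 were lower (median -0.34, adjusted p = 3.06e-06, adjusted p = 0.218 with an estimated correlation), and SOCS3 (-1.53) and PIM1 (-1.07) fell. Of 16 MAPK feedback and immediate early genes 15 were lower (median -0.44, adjusted p = 0.00131, adjusted p = 0.884 with an estimated correlation), and ETV4 (-1.99) fell. Of 7 mast cell and basophil genes 6 were lower (median -1.81, adjusted p = 8.43e-09, adjusted p = 0.173 with an estimated correlation), and PRG2 and CPA3 fell.

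With the block 31 genes were higher and 181 lower than with GRN163L, median normalization gave 13 and 23 and quantile normalization 8 and 31. The count of 68 fell to 0 without the GRN163L array of experiment 1, 2 without that of experiment 2, 14 without the combination array of experiment 1 and 29 with the covariate.

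The interaction asked whether the effect of both agents differed from the sum of their separate effects on the log2 scale. This reading takes the doses in the combination to equal those given alone, which the labels do not restate. No gene was called by limma, with the block or without it, and 464 had an unadjusted p below 0.05, 156 positive and 308 negative, also fewer than the 628 expected by chance. Here too the shared spread means that this count does not show an absence of change. The smallest p on the negative side were those of HLA-DRA, an antigen presentation gene (-2.90, SE 0.32, adjusted p = 0.120), UCA1, a long noncoding RNA (-1.90, SE 0.23, adjusted p = 0.120), and ETV1, a relative of ETV4 (-2.04, SE 0.27, adjusted p = 0.152). On the positive side they were those of VGLL3 (1.41, SE 0.22, adjusted p = 0.226), NCAM1 (1.53, SE 0.25, adjusted p = 0.233) and SEPTIN10 (1.73, SE 0.32, adjusted p = 0.423). Without the LY2784544 array of experiment 2 the count was 8.

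Of 19 integrated stress response genes 18 had a negative interaction, with a median of -0.99 (adjusted p = 3.25e-22, adjusted p = 0.0745 with an estimated correlation) and -0.86 and -0.73 in experiments 1 and 2. ASNS was at -1.96, DDIT4 at -1.72, SESN2 at -1.31 and CHAC1 at -1.17, and 11 members passed when adjusted over the list alone. All 7 mast cell and basophil genes were negative, with a median of -1.28 (adjusted p = 8.25e-13, adjusted p = 0.0745 with an estimated correlation), KIT at -2.69 and PRG2 at -2.39. All 16 lysosome genes were negative (median -0.26, adjusted p = 0.00177, adjusted p = 0.405 with an estimated correlation), as were 6 of 8 stem and progenitor genes (-0.20, adjusted p = 0.0339, adjusted p = 0.405 with an estimated correlation). Of 21 megakaryocyte and platelet genes 15 were positive (median 0.09, adjusted p = 4.69e-04, adjusted p = 0.123 with an estimated correlation). The BCL2 family (median -0.16) and NF-kB and inflammatory genes (0.20) passed only with the block, each at an adjusted p of 0.0484 (against 0.123 and 0.144).

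Of the 29 lists, 15 were called in no comparison. The smallest adjusted p over the 6 comparisons was 0.66 for the 18 erythroid genes, 0.23 for heme synthesis and iron, 0.184 for monocyte and macrophage, 0.252 for granulocyte, and 0.318 for telomerase and telomere genes. It was 0.184 for p53 target, 0.629 for DNA damage repair, 0.264 for ribosome biogenesis, and 0.187 for type I interferon genes. It was 0.208 for ER chaperone, 0.0668 for cytosolic heat shock, 0.585 for NRF2 target, 0.162 for fatty acid synthesis, 0.157 for endosome and scavenger uptake and 0.0783 for BCL2 family genes. Within the telomere list, TERC, the RNA template of telomerase, and ACD, a shelterin gene, fell in the combination against control, named here after their values were seen.

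**Figure D3:**
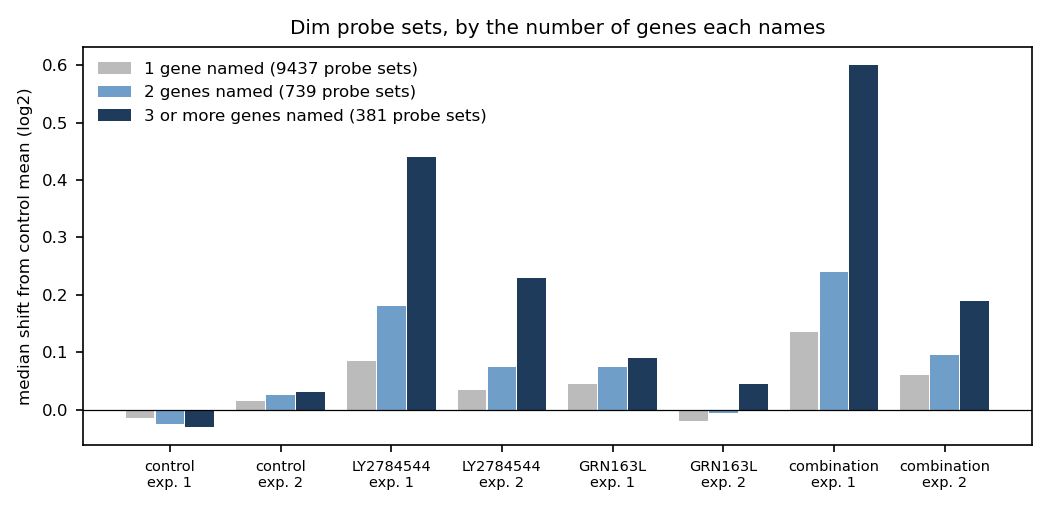
Median shift from the control mean, in log2 units, of probe sets with a control level below 6 on each array, for probe sets naming 1 gene (9437), 2 genes (739) and 3 or more genes (381). For 3 or more genes the shift was 0.44 and 0.23 with LY2784544, 0.6 and 0.19 with the combination and 0.09 and 0.045 with GRN163L, in experiments 1 and 2.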

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

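The tests of the excess of multi-gene probe sets, of the integrated stress response genes against each agent alone and against genes of the same level, and of the G2 and mitosis genes were chosen only after the results were seen, while the test of the genes beside JAK2 and the covariate test of the integrated stress response genes were set before their values were.

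A departure of the combination from the sum of the agents' separate effects, tested as the interaction, singled out 5 lists: integrated stress response genes (adjusted p = 3.25e-22), mast cell and basophil genes (adjusted p = 8.25e-13), megakaryocyte and platelet genes (adjusted p = 4.69e-04), lysosome genes (adjusted p = 0.00177) and stem and progenitor genes (adjusted p = 0.0339). None of these passed with an estimated correlation, where the smallest adjusted p was 0.0745. Signal was also found in probe sets that the comparisons do not use. Of 5478 probe sets naming no gene, 2 were called with LY2784544 (1 higher and 1 lower) and 39 with the combination (31 higher and 8 lower), each against control. Of 1487 probe sets naming several genes, 13 were called with the combination (5 higher and 8 lower).

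Dim probe sets that name several genes were higher on the LY2784544 and combination arrays. Against 1-gene probe sets of the same control level, probe sets naming 3 or more genes had a median excess of 0.37 and 0.205 with LY2784544 and 0.465 and 0.115 with the combination, in experiments 1 and 2, and of 0.045 and 0.08 with GRN163L. Genomic DNA in the RNA needs such an excess, and it is a candidate source on 3 arrays, where the smallest excess was 0.205 (95% bootstrap interval over probe sets 0.185 to 0.252), whereas a signal range set by normalization needs none and the largest was 0.465 (0.385 to 0.515); the 3 arrays were parted from the fourth after the values were seen. On the combination array of experiment 2 (0.115, interval 0.095 to 0.145) the sources cannot be told apart, because the interval holds the bound of 0.1. Also open is genomic DNA at the region of JAK2, which HEL cells are known to carry in extra copies. The excess of 21 dim neighbours was 0.073, below the 0.1 set beforehand, with 0.125 and 0.1 on the LY2784544 arrays but 0.03 and 0.01 on the combination arrays. The permutation took their shift from control instead, 0.17 against 0.1 for level-matched random lists (one-sided permutation p = 0.0305). Transcription raised by LY2784544 is open too. The excess of multi-gene probe sets differed between the experiments by 0.165 for LY2784544 and by 0.35 for the combination.

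Integrated stress response genes were higher with each agent alone (adjusted p = 0.181 for LY2784544 and 0.281 for GRN163L with an estimated correlation), and with both they were lower than with LY2784544, while the difference from GRN163L was not called (median -0.28, adjusted p = 0.378). A chance low level of the control arrays does not enter the combination minus LY2784544, with medians of -0.61 and -0.42 in experiments 1 and 2 (95% intervals over genes only -0.71 to -0.33 and -0.57 to -0.18), nor minus GRN163L, with -0.06 and -0.27 (-0.33 to 0.17 and -0.51 to -0.10). Chance in the controls and an effect of both agents cannot be told apart, because these intervals leave out the spread between arrays and neither difference passed with an estimated correlation (adjusted p = 0.336 and 0.907). A dilution by genomic DNA would move genes of one level alike, but the list's interaction lay at -0.81 (interval over genes -1.05 to -0.60) and -0.77 (-1.20 to -0.48) from genes of the same control level. The olfactory receptor covariate (median interaction -0.883) decided nothing on genomic DNA, since its own interaction was only -0.05 and what it measures was not tested.

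G2 and mitosis genes were lower in experiment 1 only, by a median of -0.84 with LY2784544, against 0.035 in experiment 2. A dilution by genomic DNA would lower genes of one level alike, but on the arrays of experiment 1 the list lay at -0.741 (interval over genes -1.049 to -0.563) with LY2784544 and at -0.738 (-1.049 to -0.615) with the combination from genes of the same control level, which argues against a dilution as the whole cause. The olfactory receptor covariate turned the medians to 0.843 and 0.771, but it would do so for any list low in experiment 1 only and decides nothing here. A difference between the cultures of the 2 experiments stays open and was not tested.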

How the results depend on the processing

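The olfactory receptor covariate and the joint removal of the LY2784544 and combination arrays of experiment 1 were chosen only after the results were seen. The cause of a difference was not tested except where fewer arrays or genes show it. In the order LY2784544, GRN163L and combination against control, then combination against LY2784544 and against GRN163L, then interaction, the counts of called genes were 160, 0, 436, 39, 68 and 0. With the experiment as a block they were 345, 0, 1382, 201, 212 and 0, every first call was kept, and beside these counts and the 8 list calls given above the block changed no other call. A filter at the 50th percentile gave 70 genes for LY2784544 against control. Fits on the compared groups only, which have fewer arrays, gave 79, 6, 153 and 0 in the first 4 comparisons. A 2-fold minimum left 276 genes for the combination against control. For the combination against GRN163L, median normalization gave 36 and quantile normalization 39. Without the 2 arrays of experiment 1 the counts were 6 for GRN163L and 217 for the combination against control and 12 for the combination against LY2784544. With the covariate they were 44, 0, 48, 272, 29 and 0.

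Leaving out each array in turn gave 0 to 212 genes for LY2784544, 0 for GRN163L and 57 to 538 for the combination against control. It gave 16 to 45 against LY2784544, 0 to 88 against GRN163L and 0 to 8 for the interaction, and a lone array was assumed to vary like the others. The genes shared by LY2784544 and the combination numbered 0 to 100. Lists called, in the same order, ranged over 5 to 10, 6 to 8, 6 to 9, 9 to 11, 5 to 9 and 4 to 10. With an estimated correlation 0, 0, 0, 0, 1 and 0 lists were called, and with fry 4, 0, 5, 3, 3 and 0. For the combination against GRN163L 9 lists were called without a filter and 11 with the covariate, and 8 for the interaction with the covariate. Median changes that turned sign were those of G2 and mitosis genes with LY2784544 (0.843 with the covariate) and with the combination (0.771), and of cholesterol synthesis genes with LY2784544 (0.029), with a covariate that also removes other differences between the experiments. Leaving out an array, the list's direction against other genes turned for G2 and mitosis genes with LY2784544 (median -0.865 to -0.020, turned at the latter) and for DNA replication genes in the combination against LY2784544 (-0.68 to -0.035, likewise). Of 105 calls of named genes, 58 to 105 stayed with the planned settings that leave out no single array, 30 (without the control array of experiment 2) to 92 when an array was left out and 38 with the covariate, and none turned sign. Signal near background limits what the values of dim genes can show.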

Other observations

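The lists in this part and the members named were chosen only after the results were seen, so that their p-values do not stand as independent tests. Metallothionein genes, a family of near-identical copies of which most but not all encode metal-binding proteins, were lower with each agent. Of 11 measured, 10 were lower with LY2784544 (median -0.85, camera p = 2.79e-09, p = 0.0474 with an estimated correlation), and MT1E (-1.80), MT1F (-1.59), MT1G (-1.52) and MT1L (-1.09) fell. With GRN163L 10 were lower (median -0.59, p = 1.08e-23, p = 0.01 with an estimated correlation) and none was called. With the combination 5 fell, among them MT1G (-1.57), MT1X (-1.50) and MT2A (-1.44), with a list median of -1.05 (p = 2.21e-07, p = 0.0638 with an estimated correlation). All 11 had a positive interaction (median 0.72, p = 4.42e-13, p = 0.0183 with an estimated correlation). Between the combination and LY2784544 the list's median was -0.125, with 4 of 11 higher in the combination and none called. Between the combination and GRN163L it was 0.055, with 6 of 11 higher and none called. The interaction and the falls against control share the control arrays. A chance high level of those arrays was not tested for this list and stays open.

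HLA class II genes, which serve antigen presentation and were listed here with CD74 and CIITA, were lower in the combination than with LY2784544. Of 10 measured, 8 were lower (median -0.48, camera p = 1.45e-11, p = 0.00810 with an estimated correlation). HLA-DRA changed by 1.20 with LY2784544 against control (adjusted p = 0.0460), by -1.43 with the combination against control (adjusted p = 0.0185) and by -2.62 between the combination and LY2784544 (adjusted p = 0.00301). HLA-DRB3 fell by 1.62 with the combination against control (adjusted p = 0.00465), and HLA-DPA1 changed by -0.78 (adjusted p = 0.0405). The interaction was negative for 8 of the 10 (median -0.47, p = 4.05e-11, p = 0.00626 with an estimated correlation).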
